A study of Sus scrofa with 15 samples.

How the data were processed

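Mesenteric lymph nodes of 15 pigs were profiled on 15 one-colour Affymetrix expression arrays, 1 array per pig. The labels place 3 pigs in a non-infected group and 12 in an infected group inoculated through the nose with *Salmonella* Typhimurium. Infected pigs were necropsied in groups of 3 at 8, 24 and 48 hours post-inoculation (hpi) and at 21 days post-inoculation (dpi). The non-infected pigs were necropsied 2 days before the inoculation, so no control group was sampled at the later times, and the pigs of the last group were older than the controls by more than 3 weeks. Each sample is a separate pig in the labels.

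The deposited table held 1 intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. The intensities as deposited had a mean of 500.1 on every array after the lowest and highest 2% of probe sets were left out. The values lay between 0.0696 and 36697.6, and none was at or under 0. From the experiment record of each array only the scan day, array lot, fluidics station and hybridization run were read. The table had 24123 probe sets, of which 124 control probe sets were left out of the main tests. Of the other 23999 probe sets, 10069 had 1 gene symbol in the platform annotation, 198 had several and 13732 had none. Symbols were updated through gene identifiers to the current pig annotation (Sscrofa11.1, names only) for 9961 probe sets. Probe sets with several symbols were named by no gene.

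Probe sets were kept if their value was above the array's 40th percentile on at least 3 of the 15 arrays, which left 15491 probe sets, 7639 of them with 1 symbol, from 5525 genes. Values were taken to log2 with no pseudocount, and each array was centred on its median. One linear model per probe set was fitted to all 15 arrays in 5 groups with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. The groups shared 1 estimate of the spread. Contrasts set each time point against the non-infected pigs, neighbouring time points against each other, and the mean of 8, 24 and 48 hpi against the non-infected pigs. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 from limma, and an F test covered the 4 contrasts against the non-infected pigs together. Changes are log2 fold changes ± SE with 3 arrays per group, unless stated otherwise. Detection calls were not used here, so the filter level, each array's 40th percentile, stood in for the background. A probe set at or under this level on every array of a group was taken as not well above background there, and its fold is given as a bound ("at least"). The bound set the brighter group's mean log2 value against the mean of this level over the arrays of the dimmer group, and no fold is given where it came to under 1. This rule was added after the data were seen. A fold against a group with only some of its arrays above this level is not exact. P-values set a difference between group means against the spread between pigs within groups, and the number of arrays limits the precision. That spread leaves out any difference in array lot or scan day between groups.

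The genes named were picked by a rule fixed before the data were examined. It took, per comparison, up to 12 largest rises and 12 largest falls among called probe sets with 1 symbol whose arrays did not overlap between the groups, with 1 probe set per gene (the one of smallest p), and was extended to the neighbouring time points. Ranks in this rule used the fitted changes, which have no order for genes given as a bound. Called members of the gene lists, and the genes of smallest p in the F test, were added. Each count of calls is given with a separate count, over all tested probe sets whether called or not, at an unadjusted p under 0.01 and a change of at least 2-fold. The 34 gene lists, also fixed before the data were examined, covered immune pathways, cell functions and markers of the cell types a lymph node sample could hold. Of these, 31 had at least 5 measured members and were tested with camera, with a preset correlation of 0.01 between genes, on 1 probe set per gene (the brightest). The tests of 5 comparisons against the non-infected pigs (155 tests) were adjusted together. A further 62 tests, of 24 hpi against 8 hpi and of 21 dpi against 48 hpi, were added after the array lots were seen. Camera with an estimated correlation and fry were run beside it.

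The arrays came from 2 lots that were scanned on 2 days. The non-infected, 48 hpi and 21 dpi arrays (9) were from lot 1, and the 8 and 24 hpi arrays (6) from lot 2. Comparisons of lot 2 groups with the non-infected pigs, and of 48 hpi with 24 hpi, thus cannot be told apart from lot and scan day. The comparisons of 48 hpi and 21 dpi with the non-infected pigs, of 24 hpi with 8 hpi and of 21 dpi with 48 hpi lie within a lot. Both fluidics stations held several groups, but all 3 non-infected arrays were on station 1. The 3' to 5' signal ratio of the GAPDH control probe sets was 4.29 ± 0.988 (SD, n = 3) in the non-infected arrays, 3.57 ± 0.284 at 8 hpi, 3.55 ± 0.355 at 24 hpi, 3.72 ± 0.458 at 48 hpi and 3.79 ± 0.511 at 21 dpi. That of the actin control probe sets ordered the groups differently, with 0.523 ± 0.079, 0.556 ± 0.0114, 0.659 ± 0.100, 0.471 ± 0.0544 and 0.496 ± 0.0563 in the same order. Correlations between arrays ranged from 0.918 to 0.973, and no pair of arrays was identical.

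In data simulated from the means and spreads of the 15491 probe sets, 240 probe sets were changed per time point. At a log2 change of 1, the model recovered 77.5% of 80 at 8 hpi, 65% at 24 hpi, 75% at 48 hpi and 58.8% at 21 dpi. At a log2 change of 0.5, it recovered 25%, 20%, 20% and 33.8% in the same order, and 8, 6, 6 and 10 unchanged probe sets were called. In simulated data with 3 of the 31 lists shifted by 0.5 at 48 hpi (5525 genes), camera called the 3 shifted lists and no other. The simulated genes varied independently of each other, so this run could not test the preset correlation between genes.

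Alternatives covered the scaling (as deposited, quantile, cyclic loess), pseudocounts of 16 and 50, the filter (none, 60th percentile), the trend, array weights, an adjusted p under 0.10, the replicate number and the fluidics station as blocks, fits of 6 arrays alone, and leaving out each array in turn. Fits within 1 lot, the hybridization run as a random block, and the 9 acute arrays as 1 group were added after the data were seen. Genome coordinates were not used here.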

Results

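The study asked how gene expression in the mesenteric lymph nodes, which drain the gut, changed during infection of pigs with *Salmonella* Typhimurium, a bacterium that invades the gut and its lymphoid tissue. Expression was measured in 3 non-infected pigs and in 3 infected pigs at each of 8, 24 and 48 hpi and 21 dpi. The arrays were scaled by the authors to a similar trimmed mean, and their median intensities lay between 161.9 and 197.4. Across the 4 time points, 2095 of 15491 probe sets differed from the non-infected pigs in at least 1 contrast (F test, limma, adjusted p under 0.05). The 8 and 24 hpi arrays were of another lot than the non-infected ones, so this count does not tell lot from infection. Among the 10 named genes of smallest p-value, with probe sets that lack a single symbol left out, were S100A9, which encodes a calcium-binding protein abundant in neutrophils, the chemokine receptor-like gene CCRL2, TREM1, HK3 and GBP1. The others were LOC100524999, GNG10, HNRNPA1, PPP3CA and FOXN3. HNRNPA1 (-1.44 and -0.99), PPP3CA (-1.24 and -0.97) and FOXN3 (-0.62 and -0.82) were lower at 8 and 24 hpi. At 48 hpi and 21 dpi these genes lay between -0.10 and 0.26.

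**Figure D1:**
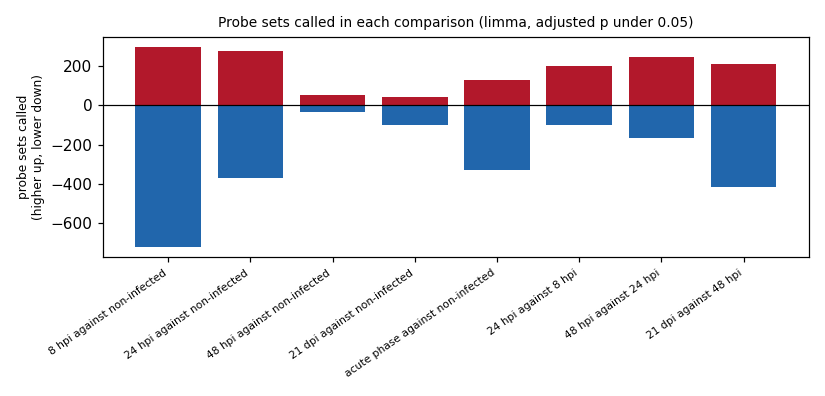
Number of probe sets called per comparison (limma, adjusted p under 0.05), with probe sets that were higher drawn above 0 and those that were lower drawn below 0. The 48 hpi comparison had the fewest calls (84) and the 8 hpi comparison the most (1019).

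At 8 hpi, genes of mitochondrial respiration and of protein degradation were lower than in the non-infected pigs. Of 28 measured oxidative phosphorylation genes, 13 fell and none rose, and the list passed camera (adjusted p = 4.89e-07; adjusted p = 0.42 with an estimated correlation). ATP5J fell by 0.71 ± 0.11, NDUFB5 by 0.60 ± 0.10 and NDUFS1 by 0.56 ± 0.10. Of 29 proteasome genes 10 fell, among them PSMA2 (-0.66 ± 0.12) and PSMA3 (-0.50 ± 0.08), and this list passed too (adjusted p = 8.92e-06; adjusted p = 0.478 with an estimated correlation). Adjusted over the list alone, 22 oxidative phosphorylation and 18 proteasome genes were lower. These falls were not particular to 8 hpi, and all rest on the same 3 non-infected pigs. At an unadjusted p under 0.05, 22, 12, 7 and 18 oxidative phosphorylation genes were lower at 8, 24 and 48 hpi and 21 dpi. For the proteasome these were 19, 13, 3 and 15, with none higher in either list. From 8 to 24 hpi limma called no gene of either list. At 8 hpi, TREM1, an activating receptor of myeloid cells, was at least 1.32-fold lower (adjusted p = 0.0307, limma). TYROBP fell by 0.88 ± 0.15, and the metalloreductase gene STEAP4 fell by 1.82 ± 0.47.

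Genes that rose at 8 hpi included the carbonic anhydrase gene CA3 (3.76-fold, 1.91 ± 0.46), EDF1 (1.35 ± 0.29) and EGR1, an immediate early transcription factor (1.28 ± 0.33). NEK3, JUP, EDC4 and APBB1 rose between 2.21 and 2.42-fold. CA3 and EDC4 were above the filter level on 2 of the 3 non-infected arrays, and NEK3 and JUP on 1. The matrix gene TNXB was at least 1.91-fold, MYLK, a kinase of smooth muscle contraction, at least 1.62-fold and PTOV1 at least 1.46-fold higher (adjusted p = 0.0341, 0.0344 and 0.0498, limma). In the adipocyte list 2 of 12 genes rose, FASN of fatty acid synthesis (2.17-fold) and ACSL1 (0.84 ± 0.21). In the fibroblast and extracellular matrix list 3 of 27 rose, THBS1 (1.06 ± 0.17), COL6A2 (0.81 ± 0.17) and BGN (1.10 ± 0.30). Both lists passed camera (adjusted p = 0.00175 and 0.00303), with adjusted p = 0.509 and adjusted p = 0.553 with an estimated correlation, and each had 3 higher genes adjusted over the list alone. Among blood and lymphatic endothelial genes 1 of 16 rose, with 5 higher and 0 lower at an unadjusted p under 0.05. Among smooth and striated muscle genes 1 of 9 rose, with 2 higher and 1 lower. STAT6, which transmits interleukin 4 signals, rose by 0.93 ± 0.14, and CD74, the MHC class II invariant chain, by 0.69 ± 0.11. In the MHC class II list 1 of 16 genes rose and 2 fell.

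HNRNPA1, an RNA-binding protein of splicing, was 2.71-fold lower, PPP3CA, a calcineurin subunit, 2.37-fold, RPL17 2.76-fold, RPL32 2.29-fold, RPS6 2.28-fold and SRSF1 2.34-fold. CYP3A29 fell by 1.90 ± 0.50 and VNN2 by 1.34 ± 0.37, and these genes and STEAP4 were above the filter level on 2 of the 3 arrays at 8 hpi. Probe sets of a gene differed: 2 of the 7 for EF1ALPHA, a translation elongation factor, fell (-1.80 and -1.58) and none of the other 5 passed, RPL12 fell by 1.49 in 1 probe set and 0.27 in the other, and the 3 of FASN gave 1.12, 0.97 and 0.45, the last not passing. Over the 57 measured ribosomal protein genes the median change was -0.14 and 4 fell, with 9 lower adjusted over the list alone. That list's direction (adjusted p = 0.000308; adjusted p = 0.706 with an estimated correlation) turned after cyclic loess normalization, where its median was 0.04.

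In all, 1019 probe sets were called at 8 hpi, 299 higher and 720 lower, 72 of them by at least 2-fold. Counted separately over all tested probe sets, 98 had an unadjusted p under 0.01 and a 2-fold change. Of the 1019, 1014 had arrays that did not overlap between the groups, against 27.2% of all probe sets and 10% by chance. The test that called them picks out separated groups, so this is not separate evidence for them. The split depended on the scaling, with 503 higher and 383 lower as deposited, 369 and 324 after quantile normalization, and 397 and 326 after cyclic loess. Without each array in turn the count was 330, 469 and 460 (non-infected replicates 1 to 3) and 839, 358 and 358 (8 hpi replicates 1 to 3). The fit of the 6 arrays alone called 196, and group and array lot cannot be told apart here.

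At 24 hpi, genes of inflammation and of the interferon response were higher than in the non-infected pigs. S100A9 rose 13.6-fold (3.76 ± 0.54), the pattern recognition gene PTX3 11.4-fold (3.51 ± 0.55) and IL1B, a central inflammatory cytokine, 6.76-fold (2.76 ± 0.61). IFNG, the cytokine that activates macrophages, rose 2.88-fold (1.53 ± 0.28). The chemokine gene CXCL9 rose 2.84-fold, and SLC11A1, a metal transporter of the phagosome that limits growth of *Salmonella*, was at least 2.30-fold higher (adjusted p = 0.00366, limma). Among the non-infected arrays S100A9 was above the filter level on 2 of 3, and PTX3 and this IL1B probe set on 1. The folds of PTX3 and IL1B thus rest on signals mostly under it and are not exact.

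Of 16 measured genes of the interferon gamma and Th1 list, 8 rose and none fell (adjusted p = 1.11e-08; adjusted p = 0.295 with an estimated correlation). WARS rose by 1.58 ± 0.25 in its brightest probe set and 1.86 ± 0.24 in another, GBP2 by 1.42 ± 0.21, IRF1 by 1.10 ± 0.17 and GBP1 by 0.79 ± 0.11. Adjusted over the list alone, 10 were higher. In the interferon alpha and beta list 4 of 21 genes rose, including ISG20 (1.42 ± 0.29) and IRF7 (1.31 ± 0.30), with adjusted p = 1.24e-08, and adjusted p = 0.42 with an estimated correlation. In that list 12 were higher adjusted over the list alone. The inflammatory cytokine list had 4 rises in 26 genes, IL15 (0.96 ± 0.14), IL1B (2.03 ± 0.45 in its brightest probe set), CEBPB (1.18 ± 0.29) and CCL4 (0.82 ± 0.21), with adjusted p = 5.19e-06, and adjusted p = 0.295 with an estimated correlation, and with 10 higher and 1 lower adjusted over the list alone. SOCS1, an inhibitor of cytokine signals, rose 3.08-fold, FAM26F 2.86-fold and TMEM140 3.14-fold, with SOCS1 above the filter level on 2 and TMEM140 on 1 of the 3 non-infected arrays. TMEM176A was at least 1.90-fold and DPM2 at least 1.53-fold higher (adjusted p = 0.0316 and 0.0475, limma). TNFSF10, a death ligand, rose by 1.32 ± 0.23, DEFB1, an antimicrobial peptide, by 1.12 ± 0.24 and TAP1, which loads peptides on MHC class I, by 1.23 ± 0.25.

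Cell division genes moved the other way at 24 hpi. Of 30 measured cell cycle genes 11 fell and none rose (adjusted p = 1.54e-09; adjusted p = 0.319 with an estimated correlation), and 20 were lower when adjusted over the list alone. STMN1 fell by 0.60 ± 0.07, TOP2A by 0.61 ± 0.11, PCNA by 0.60 ± 0.11 and CCNB1 by 0.58 ± 0.11. The replication gene POLE2 was 2.23-fold lower. Falls in the cell cycle list were not particular to 24 hpi, as 5 genes fell at 8 hpi, of the same lot, 1 at 48 hpi and 0 at 21 dpi. From 8 to 24 hpi, within that lot, 1 was called lower, with 14 lower and 1 higher at an unadjusted p under 0.05. At 24 hpi, of 4 measured B cell genes, too few for a list test, BLNK (-0.43 ± 0.08), SPIB (-0.76 ± 0.17) and BTK (-0.45 ± 0.12) fell. CD1.1 fell by 1.11 ± 0.20. CALML4 was 2.56-fold, RGS5 2.11-fold and RNF128 at least 1.72-fold lower (adjusted p = 0.028 for RNF128, limma). Single probe sets of EF1ALPHA, RPL12, RPL23, RPL17, RPS6 and RPS25 were between 2.01 and 3.88-fold lower (RPS25 above the filter level on 1 of the 3 arrays at 24 hpi), while the other RPL12 probe set, at -0.18, did not pass.

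The 24 hpi comparison called 648 probe sets (122 by at least 2-fold), 279 higher and 369 lower (374 and 293 as deposited, 362 and 264 after cyclic loess, 323 and 286 after quantile normalization). Over all tested probe sets, 173 had an unadjusted p under 0.01 and a 2-fold change. Without each array in turn the count of calls was 274, 395 and 148 (non-infected replicates 1 to 3) and 288, 568 and 240 (24 hpi replicates 1 to 3), and the fit of the 6 arrays alone called 76. As at 8 hpi, group and array lot cannot be told apart.

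The 24 and 8 hpi arrays shared a lot and scan day, and inflammatory and interferon response genes were higher at 24 hpi. CXCL9 was 3.83-fold higher at 24 than at 8 hpi, ISG20 3.73-fold and the hexokinase gene HK3 3.71-fold. IFNG rose 4.18-fold, the neutrophil chemoattractant CXCL8 3.78-fold and STEAP4 8.66-fold, each above the filter level on 2 of the 3 arrays at 8 hpi. S100A9 (5.18 ± 0.54) and PTX3 (3.62 ± 0.55) were above it on 1 of these 3, so their changes rest on signals mostly under it. IL1B was at least 3.43-fold, TREM1 at least 2.96-fold, SLC11A1 at least 2.18-fold and the matrix gene VCAN at least 1.94-fold higher (adjusted p = 0.0254, 0.0036, 0.00766 and 0.00404, limma). For SAA2, an acute phase gene, 1 probe set was at least 1.19-fold higher (adjusted p = 0.0345, limma) and another fell by 0.47 ± 0.09.

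Between 8 and 24 hpi, 10 of 21 interferon alpha and beta genes rose (adjusted p = 8.54e-17; adjusted p = 0.114 with an estimated correlation), among them IFIT3 (1.72 ± 0.28) and ZBP1 (1.42 ± 0.24). Against the non-infected pigs, whose arrays were of the other lot, that list had been lower at 8 hpi (adjusted p = 0.0125; adjusted p = 0.706 with an estimated correlation), with a median of -0.45 and 1 of 21 genes above 0. There EIF2AK2 fell by 0.56 ± 0.12, 3 genes were lower adjusted over the list alone and 9 at an unadjusted p under 0.05. Without non-infected replicate 2 or 8 hpi replicate 3 that lower level did not pass (adjusted p = 0.0602 and 0.0891). From 8 to 24 hpi 9 of 16 interferon gamma and Th1 genes rose, led by GBP1 (1.12 ± 0.11), GBP2 (1.86 ± 0.21) and IRF1 (1.24 ± 0.17), with adjusted p = 3.2e-11, and adjusted p = 0.0761 with an estimated correlation. Of 5 neutrophil genes 3 rose, S100A9, ALOX5AP (1.21 ± 0.22) and CHI3L1 (1.15 ± 0.26), with adjusted p = 0.00926, and adjusted p = 0.11 with an estimated correlation. In these 3 lists 20, 10 and 3 genes were higher at 24 than at 8 hpi adjusted over the list alone. CHI3L1 was above the filter level on 2 of the 3 arrays at 8 hpi. Of 26 inflammatory cytokine genes 4 rose and 1 fell (adjusted p = 1.19e-05; adjusted p = 0.11 with an estimated correlation), with 9 higher and 1 lower adjusted over the list alone. CASP1, the inflammasome protease, rose by 1.03 ± 0.20 and TLR4, the receptor for bacterial lipopolysaccharide, by 0.85 ± 0.18. CA3 was 2.96-fold, FASN 2.11-fold, IGF1R 2.03-fold and ADCK2 at least 1.39-fold lower at 24 hpi (adjusted p = 0.0302 for ADCK2, limma), and LOXL1, SLC25A21, FHOD1, MGLL, MAGED1, PIP5K1A and SEPT4 were between 1.74 and 1.99-fold lower, with CA3 and SLC25A21 above the filter level on 2 of the 3 arrays at 24 hpi. Of 302 called probe sets (113 by at least 2-fold) 201 were higher and 101 lower (163 and 141 as deposited, 192 and 148 after cyclic loess, 198 and 170 after quantile normalization). By the separate count, 184 of all tested probe sets had an unadjusted p under 0.01 and a 2-fold change. The count of calls was 236, 91 and 79 without 8 hpi replicates 1 to 3 and 96, 571 and 79 without 24 hpi replicates 1 to 3. Within lot 2 alone it was 47, and 50 with the hybridization run as a block.

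**Figure D2:**
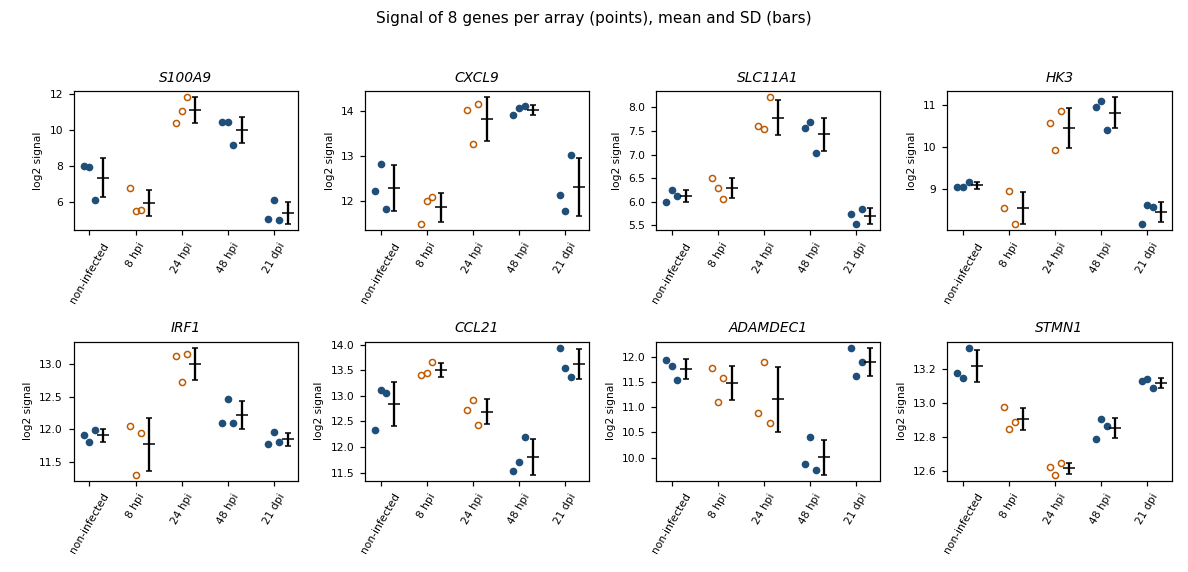
Median-centred log2 signal of 8 genes in each array against group (points), with the mean and SD (bars, n = 3); open points are arrays of lot 2. S100A9 was 13.6-fold higher at 24 hpi and 6.42-fold higher at 48 hpi than in the non-infected pigs, where 2 of 3 arrays were above the filter level, and CCL21 and ADAMDEC1 were lower at 48 hpi.

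At 48 hpi, with arrays of the same lot as the non-infected pigs, genes of complement, 2 neutrophil genes and the chemokine gene CXCL9 were higher. S100A9, above the filter level on 2 of the 3 non-infected arrays, rose 6.42-fold (2.68 ± 0.54), HK3 3.32-fold (1.73 ± 0.24), CXCL9 3.29-fold (1.72 ± 0.30) and CHI3L1, a chitinase-like protein of neutrophils and macrophages, 2.99-fold (1.58 ± 0.26). SLC11A1 was at least 1.80-fold higher (adjusted p = 0.0346, limma). ADA2 rose 2.62-fold, TNS3 2.08-fold, STX11 2.05-fold, the lysosomal phosphatase gene ACP2 2.02-fold and CCRL2 1.98-fold. The uncharacterised loci LOC100524999 and LOC100522401 rose 2.07 and 1.90-fold.

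At 48 hpi 4 of 18 measured complement and acute phase genes rose and none fell. C3, the central component, rose by 0.88 ± 0.11, C2 by 0.85 ± 0.17, C1R by 0.70 ± 0.13 and SERPING1 by 0.70 ± 0.13. There were 7 higher genes adjusted over the list alone (adjusted p = 4.38e-05; adjusted p = 0.31 with an estimated correlation). In the MHC class II list 1 of 16 genes rose, SLA-DOA (0.64 ± 0.13), with 6 adjusted over the list alone and a median of 0.20 (adjusted p = 4.22e-06; adjusted p = 0.119 with an estimated correlation). Of 5 neutrophil genes 2 rose, also adjusted over the list alone, S100A9 and CHI3L1 (adjusted p = 0.0169; adjusted p = 0.295 with an estimated correlation). Of 19 macrophage and monocyte genes limma called none (5 higher and 2 lower at an unadjusted p under 0.05), with 1 higher adjusted over the list alone, and the list passed camera (adjusted p = 0.0471; adjusted p = 0.62 with an estimated correlation). STAT6 rose by 0.73 ± 0.14.

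CCL21, a chemokine of lymphatic endothelium that guides T cells and dendritic cells, was 2.04-fold lower at 48 hpi (-1.03 ± 0.21). It was the 1 of 16 blood and lymphatic endothelial genes that fell, also adjusted over the list alone, and that list did not pass (adjusted p = 0.755). The fibroblast and extracellular matrix list went up, with 21 of 27 genes above 0 (adjusted p = 0.000412; adjusted p = 0.511 with an estimated correlation). In that list limma called no gene (6 higher and 1 lower at an unadjusted p under 0.05), with 3 higher and 1 lower adjusted over the list alone. ADAMDEC1 was 3.37-fold lower (-1.75 ± 0.27), RBM3, a cold-inducible RNA-binding protein, 2.31-fold, CPQ 2.18-fold, C3H2orf40 2.17-fold, ALDH1A1, which makes retinoic acid, 2.12-fold, RARRES1 2.03-fold and PHLDA3 2.03-fold. DAPL1, SC5D, ACOT6 and PROCR fell between 1.59 and 1.77-fold, and STMN1 fell by 0.36 ± 0.07.

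At 48 hpi 84 probe sets were called (32 by at least 2-fold), 52 higher and 32 lower (93 and 31 after cyclic loess, 78 and 29 after quantile normalization), and 86 within lot 1 alone. A 2-fold change at an unadjusted p under 0.01, called or not, was seen in 80. Without each array in turn the count of calls was 25, 55 and 8 (non-infected replicates 1 to 3) and 25, 8 and 21 (48 hpi replicates 1 to 3). Of 31 called genes of the rule, C3 and LOC100524999 were called in each of these 6 fits.

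From 24 to 48 hpi, which differ in lot, PTX3 was 7.58-fold lower at 48 hpi, IFNG 2.35-fold, PLSCR1 2.80-fold and HP, which binds haemoglobin, at least 2.54-fold (adjusted p = 0.0432 for HP, limma). GNLY, a peptide of cytotoxic cells, was 4.60-fold higher, CIT at least 1.25-fold and PTPN6 at least 1.07-fold (adjusted p = 0.00722 and 0.0334 for CIT and PTPN6, limma). The probe sets of EF1ALPHA, RPL17, RPL12, RPL23 and RPS6 named above were between 2.53 and 4.04-fold higher. The comparison called 412 probe sets (59 by at least 2-fold), 248 higher and 164 lower, and 108 of all tested probe sets had an unadjusted p under 0.01 and a 2-fold change. The count of calls was 83, 273 and 212 without 24 hpi replicates 1 to 3 and 93, 72 and 61 without 48 hpi replicates 1 to 3.

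At 21 dpi, genes of monocytes and macrophages were lower than in the non-infected pigs. CCR3, a receptor of eosinophils, was 4.34-fold lower, RETN 4.19-fold, ALOX5AP of leukotriene synthesis 3.00-fold, CCR1 2.77-fold and CD300C 2.39-fold. STEAP4 was at least 5.68-fold lower, SDS, serine dehydratase, at least 5.28-fold and TREM1 at least 1.32-fold (adjusted p = 0.00467, 0.0193 and 0.00128, limma). VNN2 was at least 2.17-fold, FCN1, a lectin of monocytes, at least 2.03-fold and QPCT at least 1.58-fold lower (adjusted p = 0.0425, 0.0435 and 0.0387, limma).

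Of 19 measured macrophage and monocyte genes 6 fell and none rose at 21 dpi, among them CD163 (-1.22 ± 0.21), MARCO (-1.16 ± 0.19), TYROBP (-0.96 ± 0.15) and AIF1 (-0.82 ± 0.16). Adjusted over the list alone 11 were lower and 1 higher (adjusted p = 0.000102; adjusted p = 0.416 with an estimated correlation). In the neutrophil list, ALOX5AP was the 1 of 5 genes that fell, with all 5 lower when adjusted over the list alone (adjusted p = 0.000412; adjusted p = 0.119 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.26, with none of 28 called by limma, 18 lower at an unadjusted p under 0.05 and 15 lower adjusted over the list alone (adjusted p = 8.11e-06; adjusted p = 0.478 with an estimated correlation). TIMP2 (-1.02 ± 0.16) and COL15A1 (-0.59 ± 0.12) were the 2 of 27 fibroblast and extracellular matrix genes that fell, with 1 higher and 5 lower adjusted over the list alone, and that list did not pass (adjusted p = 0.59). FTH1 of iron storage (-0.40 ± 0.08) and ANXA1 (-1.06 ± 0.21) fell.

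Rises at 21 dpi were smaller. C4A of the complement cascade rose 1.89-fold (0.92 ± 0.15), C3 1.54-fold (0.62 ± 0.11), the complement receptor gene CR1 1.52-fold, STAT6 1.62-fold and TNS3 1.65-fold. TMEM265, PRRC2C, MACF1, BCOR, HIVEP2, ABLIM1 and TMEM131 rose between 1.42 and 2.09-fold.

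At 21 dpi 144 probe sets were called (27 by at least 2-fold), 44 higher and 100 lower (87 and 68 as deposited, 70 and 59 after quantile normalization, 83 and 68 after cyclic loess), with 60 within lot 1 alone and 9 with the fluidics station as a block. Called or not, 86 had an unadjusted p under 0.01 and a 2-fold change. Without each array in turn the count of calls was 23, 21 and 31 (non-infected replicates 1 to 3) and 16, 10 and 126 (21 dpi replicates 1 to 3). TREM1, STEAP4, ALOX5AP and CD300C were called in each of these 6 fits.

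**Figure D3:**
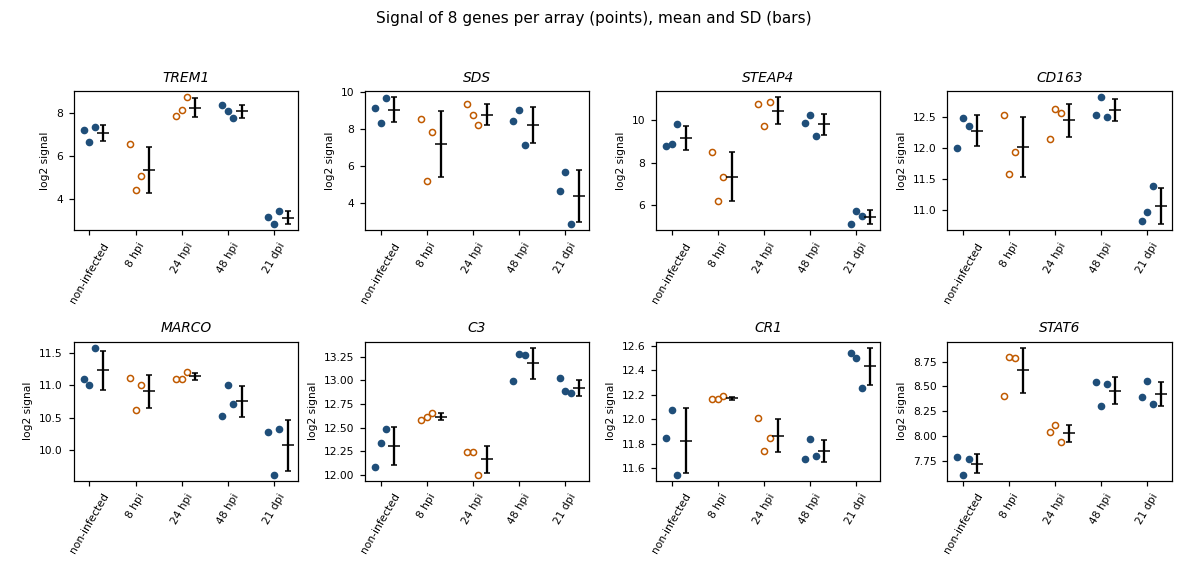
Median-centred log2 signal of 8 genes in each array against group (points), with the mean and SD (bars, n = 3); open points are arrays of lot 2. TREM1, which was not above the filter level at 21 dpi, was at least 1.32-fold lower there than in the non-infected pigs and at least 2.62-fold lower than at 48 hpi, and C3 was 1.54-fold higher at 21 dpi.

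From 48 hpi to 21 dpi, within 1 lot, inflammatory and neutrophil genes fell. S100A9 was at least 10.2-fold lower at 21 dpi, STEAP4 at least 8.91-fold, SDS at least 2.94-fold and TREM1 at least 2.62-fold (adjusted p = 0.000303, 0.00015, 0.0126 and 4.17e-05, limma). A SAA2 probe set was at least 2.43-fold, FCN1 at least 2.02-fold and PTX3 at least 1.18-fold lower (adjusted p = 0.000559, 0.0156 and 0.0223, limma). CHI3L1 changed by -2.74 ± 0.26, but it was above the filter level on 1 of the 3 arrays at 21 dpi, so its change rests on signals mostly under it. HK3 was 5.14-fold lower, TIMP1 4.87-fold and CCR1 4.51-fold. Genes that were low at 48 hpi were higher at 21 dpi: CCL21 3.50-fold (1.81 ± 0.21), ADAMDEC1 3.71-fold, C3H2orf40 2.96-fold (1.56 ± 0.16) and RARRES1 2.43-fold. HTRA4, OSBPL3, PADI2, STMN2, NDUFA1, FAM162B and HMCES rose between 2.33 and 3.94-fold, with OSBPL3, PADI2 and FAM162B above the filter level on 1 of the 3 arrays at 48 hpi, and GPR1 was at least 1.84-fold higher (adjusted p = 0.0395 for GPR1, limma).

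Neutrophil, iron and antimicrobial, and MHC class II lists passed from 48 hpi to 21 dpi with an estimated correlation too. Of 5 neutrophil genes 4 fell (adjusted p = 3.18e-06; adjusted p = 0.0231 with an estimated correlation), including NCF1 (-0.85 ± 0.22). Of 14 iron and antimicrobial genes 9 fell, including NCF4 (-0.83 ± 0.15), FTL (-0.40 ± 0.08) and SLC11A1 (at least 1.71-fold), with adjusted p = 1.13e-05, and adjusted p = 0.0231 with an estimated correlation. Of 16 MHC class II genes 6 fell, including SLA-DMB (-0.81 ± 0.14), SLA-DOA (-0.71 ± 0.13) and IFI30 (-0.55 ± 0.10), with adjusted p = 2.65e-07, and adjusted p = 0.0244 with an estimated correlation. Of 19 macrophage and monocyte genes 10 fell, including CD163 (-1.56 ± 0.21) and FCER1G (-1.11 ± 0.20), and 1 rose, APOE (0.75 ± 0.16) (adjusted p = 4.44e-07; adjusted p = 0.114 with an estimated correlation). In the interferon alpha and beta list 7 of 21 fell, including IFIT3 (-1.53 ± 0.28) and IFIT2 (-1.83 ± 0.36), with adjusted p = 1.48e-07, and adjusted p = 0.288 with an estimated correlation. Of 26 inflammatory cytokine genes 7 fell (adjusted p = 3.01e-05; adjusted p = 0.114 with an estimated correlation), with 13 lower adjusted over the list alone. Adjusted in the same way, 4, 9, 11, 13 and 14 genes of the 5 lists before it were lower, and 1 iron and antimicrobial gene and 1 macrophage gene were higher. The comparison called 630 probe sets (214 by at least 2-fold), 213 higher and 417 lower, and 619 within lot 1 alone, while 277 of all tested probe sets had an unadjusted p under 0.01 and a 2-fold change. The count of calls was 290, 281 and 500 without 48 hpi replicates 1 to 3 and 359, 294 and 584 without 21 dpi replicates 1 to 3.

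Across the acute phase, taken as the mean of 8, 24 and 48 hpi, 458 probe sets (21 by at least 2-fold) differed from the non-infected pigs, 130 higher and 328 lower (215 and 174 as deposited, 150 and 130 after quantile normalization, 190 and 141 after cyclic loess). In the separate count over all tested probe sets, 44 had an unadjusted p under 0.01 and a 2-fold change. TMEM176A was at least 1.47-fold higher (adjusted p = 0.0444, limma). EDF1 rose 2.13-fold, TCF7L2 2.00-fold, TNS3 1.76-fold, the lipid transfer gene PLTP 1.74-fold, IRF2 1.64-fold and STAT6 by 0.66 ± 0.11. POLE2 was 1.74-fold lower, ALDH1A1 1.71-fold, PHF6 1.59-fold, CLIC1 1.53-fold and POLR2B fell by 0.59 ± 0.08. Of 30 cell cycle genes 5 fell, 14 adjusted over the list alone (adjusted p = 7.86e-05; adjusted p = 0.478 with an estimated correlation). These 458 come from a fit in which differences between time points do not count as spread. With the 9 acute arrays as 1 group none was called by limma, with 2381 at an unadjusted p under 0.05. Without each array in turn the count was 13, 142 and 2 (non-infected replicates 1 to 3), 529, 357 and 314 (8 hpi), 370, 456 and 370 (24 hpi) and 265, 313 and 269 (48 hpi).

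Of the 155 list tests against the non-infected pigs, 58 passed camera with the preset correlation, none with an estimated one, and 32 passed fry. When the 15 arrays were regrouped at random, 13 of 100 groupings, the real one included, gave at least 58, with a median of 36 over the others. The number of passing lists thus did not stand apart from that of random groups, although these mix arrays of groups that can differ. Each list above is given with its count of called members.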

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

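The tests of the array lot as the whole cause and as part of it, of intensity-dependent scaling, of the fluidics station and of cell numbers, and the form of the regrouping test for the acute phase, were chosen only after the results were seen.

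The effects of neighbouring time points differed, by direct tests of the difference, for 302 probe sets between 8 and 24 hpi, 412 between 24 and 48 hpi and 630 between 48 hpi and 21 dpi. CCRL2, a chemokine receptor-like gene, was lower than in the non-infected pigs at 8 hpi (-0.77), higher at 24 hpi (0.87) and 48 hpi (0.99) and lower at 21 dpi (-1.02), and passed each time. LOC100524999 had the same order of signs (-0.64, 0.60, 1.05 and -0.77). Outside the pig genes, 1 control probe set, for a spiked-in bacterial transcript (dap), was higher at 8 hpi than in the non-infected pigs (0.69, adjusted p = 0.0482, limma; mean signal 4457 against 2493).

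At 8 hpi 720 probe sets were lower than in the non-infected pigs, with a median of -0.49. A change of single probe sets is argued against as the whole cause, since 77.8% of 194 other probe sets of the same genes were lower too (53.9% of all probe sets were), although EF1ALPHA and RPL12 had probe sets that differed. The 194 came from 132 genes and had a median of -0.21, against -0.51 for the called probe sets of these genes. The direction was thus shared more than the size. Scaling may account for part of the calls, as 44.9% were still called after cyclic loess. There all 720 were still lower, with a median of -0.39 (median SE 0.112 before and 0.107 after). Values as deposited, which differ from the centred ones by the same shift at every intensity, gave these 720 a median of -0.41. In that setting 383 probe sets were called lower. The loss of calls is thus not particular to scaling that depends on intensity, and part of the 720 rests on the median centring. As the whole cause, array lot and scan day would shift the 720 as much between other groups that differ in lot. At 24 hpi against the mean of 48 hpi and 21 dpi their median was -0.060 (SD 0.374 between probe sets). The 720 were picked on the 8 hpi and non-infected arrays, however, so a smaller value is due in other arrays under any cause. In the non-infected arrays, of the same lot as 48 hpi and 21 dpi, their medians against that mean were 0.234, 0.217 and 0.204. At 8 hpi they were -0.196, -0.353 and -0.241. The test thus does not decide on lot and scan day as the whole cause. As part of the cause, or beside an opposite difference between those times, lot and scan day cannot be told apart from infection. Of the 720, 62.5% were lower at 24 hpi than in that mean, between the bounds of 60% and 80% set for the test, and 49.6% of all probe sets were.

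Of the 369 probe sets lower at 24 hpi than in the non-infected pigs (median -0.55), 85.6% were also lower at 8 hpi than in the mean of 48 hpi and 21 dpi, with a median of -0.22 there (SD 0.378 between probe sets), against 54.1% of all probe sets, and lot cannot be told apart from infection in this set.

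At 21 dpi 100 probe sets were lower than in the non-infected pigs, with a median of -0.69. With the fluidics station as a block the median kept 97.7% of its size (-0.67), but the median SE rose from 0.125 to 0.139 and 6 of the 100 were still called. The median kept at least 91.0% without each of the 3 non-infected pigs in turn (-0.67, -0.63 and -0.71). The 100 were called on these same arrays, however, and none of the 144 calls had overlapping groups. This includes 21 dpi replicate 3, which was on station 1 like the non-infected arrays. A large loss was thus unlikely from the start in either test. Neither decides, on the fluidics station or on a single non-infected pig as the cause. Fewer neutrophils and macrophages in the node may contribute: 83.3% of the measured list members of these cells, 20 of 24, were lower, and 21 were after cyclic loess. Of all probe sets 52.0% were lower, and 6 macrophage members and 1 neutrophil member are themselves among the 100. Lower expression per cell would look alike, and the higher age of these pigs, with no control group of that age, was not tested.

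For the comparisons of 3 arrays with 3, only 10 splits exist, so no share under 0.1 can be reached. The real split was the 1 split with as many calls each time, with 1019 against at most 2 in the others at 8 hpi, 648 against 20 at 24 hpi, 84 against 1 at 48 hpi and 144 against 3 at 21 dpi. Between neighbouring time points, the real values of 302, 412 and 630 stood against at most 2. For the F test, 1 of 100 regroupings of the 15 arrays, the real one, gave 2095 or more (highest other 100). This argues against groups that do not differ at all, but does not tell lot from infection. Regroupings that mix differing groups have a larger spread, so the size of the count is not tested.

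For the acute phase, a first test with the 9 acute arrays as 1 group gave 0 calls in the real grouping so that every other grouping gave as many. It was replaced, after this was seen, by regrouping 12 arrays in the model of 5 groups, where 1 of 100, the real one, gave 458 or more (highest other 159). These regroupings mix time points, which raises the spread, so the acute count is not taken as clear of chance. For the gene lists, 13 of 100 regroupings gave 58 or more passing tests (highest 74), so chance is not excluded for their number. These regroupings too mix arrays of groups that can differ, so they do not show how many lists would pass without any difference.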

How the results depend on the processing

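The fits within 1 lot, with the hybridization run as a block, and with the 9 acute arrays as 1 group were chosen after the data were seen. Counts of calls moved with many settings, while none of 453 called gene and comparison pairs turned its direction in a setting in which it was fitted again. The pairs were picked as calls on these same arrays, so a turn was unlikely from the start and its absence is not separate evidence. Of these 453, 383 were still called after cyclic loess, 386 after quantile normalization, 353 with the fluidics station as a block, 380 with the replicate block and 442 with array weights. In fits of 6 arrays alone 174 of 404 were still called, and with the 9 acute arrays as 1 group 0 of 49. Except for fewer arrays or a looser threshold, the cause was not tested. Detection calls were not used here. The dimmer group was at or under the filter level on all its arrays for 21 of the calls at 8 hpi, 19 at 24 hpi, 2 at 48 hpi, 10 at 21 dpi, 10 in the acute phase, 15 from 8 to 24 hpi, 10 from 24 to 48 hpi and 33 from 48 hpi to 21 dpi, and for these the data give no exact fold.

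With no filter, 47 probe sets were called at 48 hpi, 63 at 21 dpi, 151 from 8 to 24 hpi and 205 from 24 to 48 hpi. The filter at the 60th percentile gave 245 at 21 dpi, and quantile normalization 280 in the acute phase. With no intensity trend the counts were 601 at 8 hpi, 397 at 24 hpi, 20 at 48 hpi, 23 at 21 dpi, 140 in the acute phase, 146 from 8 to 24 hpi and 187 from 24 to 48 hpi. Array weights gave 149 at 48 hpi, 367 at 21 dpi, 499 from 8 to 24 hpi, 890 from 24 to 48 hpi and 1007 from 48 hpi to 21 dpi. At an adjusted p under 0.10 they were 1798, 1253, 206 and 594 at the 4 time points, 1085 in the acute phase, 622, 922 and 1059 between neighbouring time points and 3542 in the F test. Fits of 6 arrays alone gave 196, 76, 47 and 18 at the 4 time points, 47 from 8 to 24 hpi and 31 from 24 to 48 hpi.

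The fluidics station as a block gave 9 at 21 dpi and 211 in the acute phase. Within lot 1, 60 were called at 21 dpi and 552 in the F test. Within lot 2, 47 were called from 8 to 24 hpi, and 50 with the hybridization run as a block. The run as a random block, with a correlation of 0.0209 within runs, gave 85 at 21 dpi. With the 9 acute arrays as 1 group limma called 0 (smallest adjusted p = 0.059), with 2381 at an unadjusted p under 0.05. Scan day and lot could not be fitted as blocks, since each group lay in 1 of them.

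The replicate numbers were not taken to pair the pigs: of 30 pairs of arrays with the same number, 6 had deviations correlated above 0.1 (median -0.012, range -0.315 to 0.329), and 6 of 15 arrays correlated best with their own number. At 8 and 24 hpi the number coincided with the hybridization run, and the 3 pairs there had 0.182, 0.221 and -0.048, so in that comparison the replicate block is also a block for the run. The replicate block gave 53 at 21 dpi and moved no other count by over 1.5 times.

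Leaving out 1 array in turn gave 330 to 839 calls at 8 hpi, 148 to 568 at 24 hpi, 8 to 55 at 48 hpi and 10 to 126 at 21 dpi. It gave 2 to 529 in the acute phase, 79 to 571 from 8 to 24 hpi, 61 to 273 from 24 to 48 hpi, 281 to 584 from 48 hpi to 21 dpi and 1398 to 2146 in the F test. Passing list tests numbered 53 to 65, against 58 in all arrays, 0 for camera with an estimated correlation and 32 for fry.

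The list of ribosomal proteins turned its direction. Its median was -0.0071 at 8 hpi and -0.0041 at 24 hpi after quantile normalization, and 0.036 (adjusted p = 0.012) at 8 hpi, -0.00018 at 24 hpi and -0.00080 in the acute phase after cyclic loess. In 4 of these 5 the test no longer passed, and the sign of the median and that of the test differed. The cause was not tested.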

Other observations

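The comparisons of list tests between neighbouring time points were chosen after the array lots were seen.

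From 8 to 24 hpi 3 of 18 measured toll-like receptor and inflammasome genes rose, SLC11A1, CASP1 and TLR4, and from 48 hpi to 21 dpi 6 fell, among them CASP1 (-1.75 ± 0.20), TLR8 (-1.24 ± 0.26) and TLR2 (-0.71 ± 0.15). The list passed camera in both (adjusted p = 0.0176 and 0.00125), with adjusted p = 0.249 and adjusted p = 0.136 with an estimated correlation. Adjusted over the list alone, 6 were higher and 1 lower in the first and 9 lower in the other. TLR8 was above the filter level on 2 of the 3 arrays at 21 dpi. The chemokine genes CXCL8 (-2.10 ± 0.42, above that level on 2 of 3 arrays at 21 dpi) and CXCL2 (at least 1.90-fold), which attract neutrophils, and IL10 (-1.04 ± 0.22), an inhibitory cytokine, were also lower at 21 dpi than at 48 hpi. In the fibroblast and extracellular matrix list 4 of 27 genes fell over the same interval, including TIMP2 (-1.59 ± 0.16), COL15A1 (-0.88 ± 0.12) and FBLN1 (-1.15 ± 0.22), with 1 higher and 9 lower adjusted over the list alone (adjusted p = 0.00113; adjusted p = 0.424 with an estimated correlation).

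Between 24 and 48 hpi, 15 probe sets were higher and 14 lower than in the non-infected pigs at both times, where independent lists would share 0.937 and 0.762. Unchanged groups simulated against the same controls shared at most 1 in 100 simulations. With no probe set changed few can be called, so these simulations do not show how much shared controls add to lists as long as the real ones. S100A9, CXCL9, SLC11A1, HK3 and STX11 were among the shared rises, and RBM3, ALDH1A1, TES and STMN1 among the shared falls. At 8 and 24 hpi 70 were higher and 181 lower at both times (5.39 and 17.2 for independent lists, at most 1 simulated). Part of the excess can come from the shared controls, since 3 control arrays cannot be split, and at 8 and 24 hpi the lot is shared too.

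The mean of the 8 and 24 hpi groups, the 6 arrays of lot 2, differed from the mean of the 3 groups of lot 1 for 1410 probe sets, and lot and time cannot be told apart in this count. In the same direction these included 519 of the 1019 called at 8 hpi, 454 of the 648 at 24 hpi, 9 of the 84 at 48 hpi and 11 of the 144 at 21 dpi. Independent lists would share 49.9, 30.2, 3.66 and 7.02. Unchanged groups shared at most 1 in 100 simulations, but with few calls they could share little. Each comparison also uses arrays of the lot contrast, so an effect of time alone gives overlap too. With arrays that do not enter the comparison, 143 of the 1019 were also called in the same direction at 24 hpi against the mean of 48 hpi and 21 dpi (40.3 for independent lists), and 99 of the 648 at 8 hpi against that mean (7.34 for independent lists).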
